A study of Mus musculus with 6 samples.

How the data were processed

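Total RNA of the gastrocnemius of 3 young (13 weeks) and 3 old (25 months) male mice was labelled with Cy3, per the labels' protocols, and each sample was hybridised to its own array. The deposited scanner files hold an intensity per spot, background-subtracted and detrended by Agilent Feature Extraction 11.0.1.1 with the protocol GE1_1100_Jul11, per the file headers. The submitters' processing notes name Agilent Feature Extraction 9.5. The authors' deposited value table also holds an intensity per spot. Each of its 62976 values per array equalled the processed intensity divided by the array's 75th percentile over all spots, times 100 and rounded, so its scale is linear, it is not centred per gene and its direction is that of the signal. Its column medians were 6, 7, 7, 9, 7 and 6 for young replicates 1 to 3 and old replicates 1 to 3. It was used as an alternative.

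Control spots and spots flagged as non-uniform or population outliers (161 to 212 per array) were left out. The log2 of the processed signal, minus its 75th percentile over the array's non-control probes, was averaged over the spots of a probe. Values are thus relative to that percentile of the same array. Of 55681 probes, 28331 matched the RefSeq gene table of assembly GRCm38.p6 through their accession, each to 1 symbol, and 27350 did not match and kept the file's name. The array grid names mm9 as its build, so no coordinates were taken from that table. Probes well above background on at least 3 of the 6 arrays were kept (28013), and each gene was represented by its kept probe with the highest mean over all 6 arrays, giving 20907 genes, 13846 of them with a symbol. Different probes of a gene can measure different transcripts, and the larger disagreements are given where a gene is named.

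Old and young were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over the genes tested. An exact permutation test of 3 against 3 arrays cannot give a p below 0.1, so no test of single values is reported. Gene lists were tested with limma's camera (preset correlation 0.01, two-sided, adjusted over the 30 lists with at least 5 tested members), with camera on an estimated correlation and fry beside it. The 31 lists cover muscle programmes, other cell types that a muscle sample can hold, signs of handling and a sex check, and no gene was in 2 lists. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

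The main settings, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule names up to 15 increases and 15 decreases with the largest log2 difference among genes past the threshold whose old and young values do not overlap and whose name is a gene symbol. It excludes names ending in Rik and predicted-gene, clone and accession names. In each list it names the 4 members with the lowest p (3 are given for the lymphocyte and plasma cell list), and any past the threshold where these are 6 or fewer.

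The alternatives were quantile normalization, median centring, normexp background correction (offset 50), the authors' values, both other filters on dim probes, the mean of a gene's probes or every probe, eBayes with trend and robust settings, array weights, the replicate number as a block, the slide row as a block, and leaving out each array. Normexp used each spot's median signal with its local background median, in place of the mean signal that had been planned. All arrays shared 1 slide and 1 scan, so neither could act as a batch. Young replicates 1 to 3 and old replicate 1 lay in row 1 of the slide, and old replicates 2 and 3 in row 2.

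The gene and list tests were tested on simulated data for old versus young, with 20899 genes and 200 of them changed. Of 50 genes changed by each size, 8% were recovered at a log2 change of 1, 82% at 2, 92% at 3 and 98% at 5, with 12 false calls beside them. With no change there were 0 calls. Of 3 shifted lists 3 were called, and of 27 unshifted lists 0. The simulated genes varied independently, and the 3 lists were shifted by a log2 change of 1. These counts therefore do not show how often lists are falsely called when their members vary together. In the data the estimated correlation reached 0.65, in the list of atrophy genes.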

Results

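Gene expression was measured in the gastrocnemius, a calf muscle made up largely of fast fibres, of male mice at 13 weeks of age (young, 3 samples) and at 25 months (old, 3 samples). Each sample was labelled with Cy3 and hybridised to a single-colour Agilent array, all 6 on 1 slide. Between 49.9% and 54.8% of the spots that carried a gene probe were well above background, and no such spot was saturated. The number of arrays limits the precision. The labels number 3 samples per age without saying that each came from a separate animal. The p-values of single genes thus measure the spread between these samples, which may be partly technical. Over the 20907 genes tested, the Pearson correlation across genes ran from 0.981 to 0.990 within the young arrays, from 0.976 to 0.987 within the old arrays and from 0.966 to 0.982 between the ages. Old replicate 1 correlated at 0.978, 0.982 and 0.969 with young replicates 1, 2 and 3, and at 0.976 with each of old replicates 2 and 3. It was thus closer to young replicates 1 and 2 than to its own age. Genes are not independent replicates. Old replicate 1 stood apart from the other arrays, with a mean negative-control signal of 61.3 against 51.9 to 55.1 on the young arrays and a spike-in slope of 0.840 against 0.925 to 0.941 on the others. The Y-linked genes Ddx3y, Eif2s3y and Uty were well above background on all 6 arrays, with adjusted p from 0.550 to 0.726 between the ages.

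The comparison asked which transcripts differ between old muscle, described by the study as atrophied by aging, and young muscle. Transcripts of inflammatory cells were among the largest increases in old muscle. S100a8 and S100a9, the subunits of calprotectin, which neutrophils hold in abundance, were 27.9-fold and 25.9-fold higher, with log2 differences of 4.80 ± 0.31 and 4.70 ± 0.30 (SE here and throughout, 3 arrays per age). Krt18, a keratin of simple epithelia, was 63.0-fold higher (5.98 ± 0.49) and Gdf5, a ligand of the bone morphogenetic protein family, was 27.5-fold higher (4.78 ± 0.20, and 3.68 by its other probe). Among the decreases, Wif1, a secreted inhibitor of Wnt ligands, had a log2 difference of -4.14 ± 0.44, whose size is uncertain as it was well above background on only 1 of 3 old arrays, and Kera, the proteoglycan keratocan, was 9.09-fold lower (-3.18 ± 0.33).

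In all, 53 genes passed limma's moderated test at a Benjamini-Hochberg adjusted p under 0.05, 41 higher and 12 lower in old muscle. Each differed by at least 2-fold, from 1.29 to 5.98 in size on the log2 scale, and in each the 3 old and 3 young values did not overlap. Of the 20907 genes, 4561 (21.8%) were separated in this way, where the average over all splits of the arrays into 3 and 3 is 10%. Genes vary together, so a single split can lie far from that average without a difference in age. At an unadjusted p under 0.05 in limma's test there were 3021 genes (14.4%), 1268 higher and 1753 lower. Grouping young replicates 1 and 2 with old replicate 1 gave 2439 at that threshold. Of the 53 genes, 39 had a name that the fixed naming rule allows, and 6 of the 404 tested members of the gene lists were among them.

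A probe that was not well above background on any array of an age gives only a bound. Its fold is the brighter age's mean over the lowest signal that counted as well above background in the dimmer age, or over the probe's own signal where that was higher. On this basis Sirpb1a and Sirpb1b, signal-regulatory receptors of myeloid cells, were at least 5.23-fold and at least 6.33-fold higher in old muscle. The probes of Sirpb1a gave log2 differences of 3.79 and 2.81. The leukocyte glycoprotein Cd101 was at least 5.05-fold higher, the cytokine Il1b at least 2.70-fold, the metalloprotease Astl at least 2.15-fold and Stfa2l1, of the stefin family, at least 1.76-fold. For Csprs the probe tested was at least 8.13-fold higher (log2 difference 3.67), but its other kept probe, which was measured in young muscle, gave 0.17, so no bound holds for the gene. Without old replicate 1, 2 or 3 that other probe was tested and gave 0.18, 0.26 and 0.07. Sirpb1a, Sirpb1b and Csprs belong to families of near-identical genes, so their probes may not tell the members apart. The chemokine Ccl8 (log2 difference 3.64 ± 0.33), the prostaglandin-inactivating enzyme Hpgd (3.42 ± 0.39) and the actin-binding Aif1l (3.18 ± 0.32) were measured on every array. Shisal1 (3.68 ± 0.41) was well above background on 1 of 3 young arrays. Limma's adjusted p for these increases ran from 0.00190 for Gdf5 to 0.0496 for Csprs.

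The other decreases included genes of matrix, junction and nerve. Col22a1, a collagen of the junction between muscle and tendon, was 2.71-fold lower (-1.44 ± 0.15). Prima1, which anchors acetylcholinesterase in the membrane, was 4.32-fold lower (-2.11 ± 0.22). Prx, the periaxin of myelinating Schwann cells, was 2.44-fold lower (-1.29 ± 0.16) and the clock repressor Bhlhe41 was 2.70-fold lower (-1.43 ± 0.18). The fibrillar collagen chain Col11a1, not well above background on any old array, was at least 1.46-fold lower. The probe tested for the ligand Wnt16 was at least 3.06-fold lower (-2.16), but its other kept probe, measured in old muscle, gave -0.43, so this is no bound for the gene. Without young replicate 3 the other probe was tested and gave -0.64 (adjusted p = 0.703). The probes of Bhlhe41 gave -1.43 and -0.68. Limma's adjusted p for the 8 named decreases ran from 0.0263 to 0.0429.

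**Figure D1:**
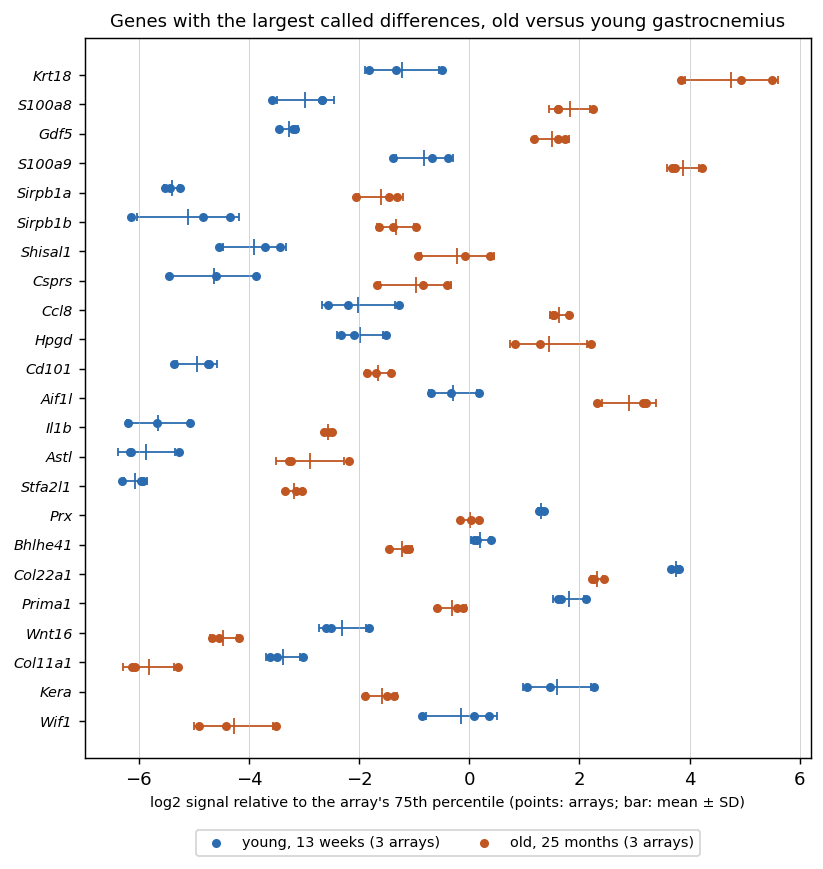
Log2 signal relative to each array's 75th percentile (x axis) for the genes with the largest increases and decreases past limma's adjusted p of 0.05 (y axis), with a point per array, blue for young and orange for old, and bars for the mean ± SD of 3 arrays. Krt18 lies at -1.22 in young and 4.76 in old muscle on average, and in no gene shown do the ages overlap.

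Normexp, whose offset compresses dim signals, shrank several log2 differences by more than 1.5 times. It gave 3.17 for Gdf5, 1.81 for Shisal1, 1.13 for Cdkn2a and -2.04 for Wif1. For the genes with a bound it gave 1.03 for Sirpb1a, 1.20 for Sirpb1b, 1.22 for Csprs, 0.97 for Cd101, 0.60 for Il1b, 0.58 for Astl, 0.52 for Stfa2l1, -0.46 for Col11a1 and -0.60 for Wnt16, each smaller than its bound above, so those bounds hold only without that offset. The mean of probes gave 1.92 for Csprs and -1.29 for Wnt16.

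The number of genes depended on single arrays. It was 10 without young replicate 1, 8 without young replicate 2, 17 without young replicate 3, 186 without old replicate 1 (91 higher, 95 lower), 6 without old replicate 2 and 1, Gdf5, without old replicate 3. Centring each array on its median called 26 higher of 42 genes and normexp background correction 38 higher of 61, beside 41 of 53 as reported. Median centring moved the median log2 difference of all genes from -0.06 to -0.21, so differences under that setting are relative to a lower centre. Old replicates 2 and 3 lay in a slide row with no young array. With the row as a block, which compares old replicate 1 with the young arrays of its own row, 41 genes passed, 22 higher and 19 lower, 12 of them among the 53. S100a8 and S100a9 were lost only without old replicate 3 (adjusted p = 0.0798 for both) among the arrays left out in turn. Over all 18 alternatives each passed in 16. Krt18 was lost without young replicate 2 or 3 (0.0639 and 0.0671) and without old replicate 2 or 3 (0.107 and 0.0892). Shisal1, Hpgd, Aif1l, Wif1, Col11a1, Wnt16, Prima1, Col22a1, Bhlhe41, Prx and Cdkn2a passed only without old replicate 1 among these fits. Of the fits without a young array, none tested Col11a1, and only that without young replicate 3 tested Wnt16. Ccl8 was lost without young replicate 2 (0.0984), old replicate 2 (0.107) and old replicate 3 (0.127). Kera was lost without young replicate 1 (0.0512) or 2 (0.104) and without old replicate 2 (0.108) or 3 (0.127). Csprs was lost whichever array was left out. The other genes with a bound that were higher in old muscle were not tested when an old array was left out, as the filter on dim probes removed them. Without a young array, Sirpb1a, Cd101 and Stfa2l1 passed each time, Il1b was lost without young replicate 2 (0.0984), and Sirpb1b and Astl did not pass.

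Of 31 gene lists fixed before the data were examined, 30 had at least 5 tested members. Limma's camera test with a preset correlation of 0.01 called 16 of them at an adjusted p under 0.05, 9 higher and 7 lower in old muscle. With that setting camera compares a list's genes with all other genes, and its p-values rest on the spread over genes. Genes are not independent replicates, so a small value does not show that a list's shift exceeds the spread between samples. With an estimated correlation between members it called 0. Calls were lost even where that correlation lay below the preset 0.01. It was -0.09 in the embryonic and regenerating fibre list and -0.02 in the Schwann cell and nerve list. The unadjusted camera p of these lists rose from 6.90e-06 to 0.00919 and from 6.19e-04 to 0.0229. A call lost under this setting therefore does not by itself show that a list's members vary together. Fry, which tests whether a list's members move on balance one way without comparing them with other genes, called 7. Members named below are those with the lowest p in their list. Unless said otherwise they did not pass the adjustment over all genes, and their values are log2 differences.

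Genes that respond to loss of innervation were higher in old muscle. Of the 17 tested members of the denervation and neuromuscular junction list, 10 rose when adjusted over the list alone and 0 over all genes. The values were 2.75 ± 0.41 for the transcription factor Runx1 (3.71 by its other probe), 2.59 ± 0.39 for Gadd45a and 2.47 ± 0.54 for myogenin (Myog). Chrng, the acetylcholine receptor subunit of fetal muscle, was at least 2.50-fold higher, being not well above background on any young array. The list rose (median 0.98, camera adjusted p = 2.50e-04), with adjusted p = 0.187 with an estimated correlation and fry adjusted p = 0.0362. The median was 0.33 with normexp, 0.60 with the mean of probes, 0.65 with the slide row as a block and 0.64 without old replicate 1 or old replicate 3. Genes of embryonic and regenerating fibres rose with it (median 1.20, camera adjusted p = 1.03e-04, and adjusted p = 0.166 with an estimated correlation). Of 11 members, 4 rose when adjusted over the list alone and 0 over all genes. They were embryonic myosin Myh3 (1.66 ± 0.28), the stress-responsive Ankrd1 (3.42 ± 0.70) and the fusion factors Mymk (1.77 ± 0.36) and Mymx (3.67 ± 0.99), which were well above background on 1 and 2 of 3 young arrays. Without old replicate 3 the median was 0.78.

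**Figure D2:**
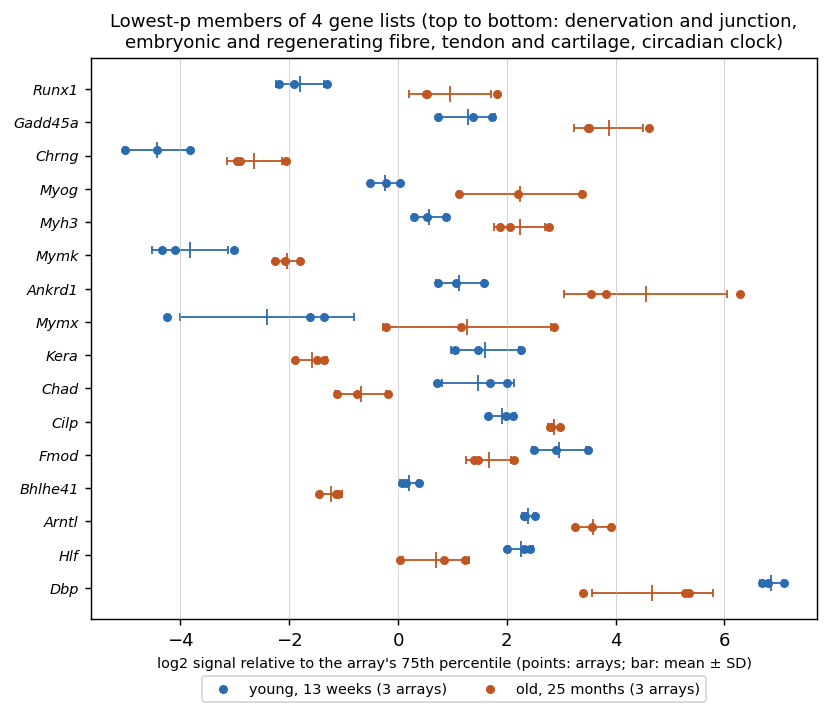
Log2 signal relative to each array's 75th percentile (x axis) for the members with the lowest p in the denervation, regenerating fibre, tendon and clock lists (y axis), a point per array, blue for young and orange for old, with bars for the mean ± SD of 3 arrays. Runx1 averages -1.80 in young and 0.95 in old muscle, and Dbp 6.86 and 4.68.

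The atrophy list of ubiquitin ligases and autophagy genes had a median of -0.01 over 20 members (camera adjusted p = 0.988). Mstn, which encodes the growth inhibitor myostatin, had a value of -1.20 ± 0.24 and was the 1 member that fell when adjusted over the list alone. Eif4ebp1 (0.47 ± 0.25), Tfeb (-0.32 ± 0.18) and Sqstm1 (0.47 ± 0.26) had an adjusted p of at least 0.427. The list was called lower with array weights (median -0.32, adjusted p = 0.0484) and higher with the slide row as a block (median 0.48, adjusted p = 8.69e-04), where old replicate 1 is the only old array that counts. The slow fibre list fell (median -0.59 over 12 members, camera adjusted p = 0.0275, adjusted p = 0.549 with an estimated correlation, fry adjusted p = 0.276). Its members Atp2a2 (-0.74 ± 0.22, and -0.21 by its other probe), Myh7b (-0.88 ± 0.31) and Tnnt1 (-0.58 ± 0.21) did not pass even over the list alone. The calcium pump regulator Sln had 3.03 ± 0.53 and rose when adjusted over the list alone. The slow fibre call was lost with quantile normalization (0.0886), with the slide row as a block (0.926), without young replicate 2 (0.118), without old replicate 2 (0.124) and without old replicate 3 (0.0978). The fast fibre list was not called (median -0.17 over 14 members). Camera used only genes with a value on every array, so its adjusted p of 0.164 leaves out Tnni2, not measured on old replicate 3. The list held Tnni2 at -1.42 ± 0.25, Mylk2 at -0.72 ± 0.21, Myh1 at -0.33 ± 0.19 and Mylpf at 1.29 ± 0.73. It was called lower with no filter (0.0351), with the slide row as a block (0.0153) and without old replicate 3 (0.0198).

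The oxidative phosphorylation and glycolysis lists shifted downwards by a small amount by camera with a preset correlation, while the fatty acid list was not called. In the oxidative phosphorylation list 29 of 30 members had a negative value, with a median of -0.27 (camera adjusted p = 3.01e-04, adjusted p = 0.391 with an estimated correlation, fry adjusted p = 0.0482), and 0 passed singly, also when adjusted over the list alone. Cycs had -1.33 ± 0.47 (-0.49 by its other probe), Ndufa9 -0.52 ± 0.19, Cox5b -0.48 ± 0.19 and Sdhd -0.38 ± 0.15. All 18 glycolysis and glycogen genes had a negative value, and again 0 passed singly, with a median of -0.26 (camera adjusted p = 0.00868, adjusted p = 0.411 with an estimated correlation, fry adjusted p = 0.0927). Pfkfb1 had -1.02 ± 0.30, Pfkm -0.33 ± 0.15, Pygm -0.31 ± 0.15 and Gpd1 -0.49 ± 0.27. Quantile normalization ended both calls (medians -0.14 and -0.10, adjusted p = 0.0783 and 0.331), and the glycolysis call was also lost without old replicate 1 (median -0.15, adjusted p = 0.104). The median of the glycolysis members, each centred on its mean over the 6 arrays, was -0.32 on old replicate 1 and -0.01 on each other old array. When all genes were split by brightness into 4 equal groups, the brightest lay 0.13 lower at the median on old replicate 1 than on the other old arrays. Median centring gave medians of -0.42 and -0.41, and the slide row as a block -0.43 for glycolysis. The fatty acid list was not called (median -0.24 over 18 members, adjusted p = 0.187), with Cpt2 at -0.44 ± 0.15, Angptl4 at 1.98 ± 0.77, Acadm at -0.44 ± 0.21 and Lpl at -0.81 ± 0.43 (-0.26 by its other probe). It was called lower with no filter (0.0351), with array weights (0.0112), without young replicate 3 (0.0182) and without old replicate 1 (0.0153).

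Among the immune lists, those of macrophages, neutrophils and antigen presentation rose. The macrophage list rose (median 0.60 over 14 members, camera adjusted p = 7.19e-06, adjusted p = 0.166 with an estimated correlation, fry adjusted p = 0.0111). Adjusted over the list alone 6 members rose, among them the complement gene C1qb (0.89 ± 0.17), Tyrobp (0.88 ± 0.17), Fcer1g (0.87 ± 0.21) and Cd68 (1.08 ± 0.27). In the neutrophil list (median 2.32 over 6 members, or 2.12 with the bounded member at its bound; camera adjusted p = 9.87e-04, adjusted p = 0.351 with an estimated correlation) S100a8 and S100a9 passed over all genes. Over the list alone Retnlg, a resistin-like neutrophil product at least 8.23-fold higher, rose too, and the antimicrobial Camp fell (-0.40 ± 0.15). With members so far apart the median was unstable. It was 0.32 with no filter, 1.26 with normexp, 1.20 with probes well above background on all arrays or with every probe, 1.08 without old replicate 1 and 0.63 without old replicate 3. Antigen presentation genes rose (median 0.36 over 12 members, camera adjusted p = 0.00260, adjusted p = 0.346 with an estimated correlation, fry adjusted p = 0.0927). H2-Eb1 had 1.25 ± 0.29 and was the 1 member that rose when adjusted over the list alone, while H2-Ab1 had 0.74 ± 0.26 and Cd74 0.59 ± 0.23. Ciita was at least 1.80-fold higher. Without old replicate 1 this list was not called (median 0.22, adjusted p = 0.0779). Its median was also 0.22 without old replicate 3, 0.21 with median centring, 0.19 with probes well above background on all arrays and 0.56 with every probe. The lymphocyte and plasma cell list was not called (median -0.23 over 8 members, adjusted p = 0.541), with Jchain at 1.41 ± 0.49, Cd2 at -0.45 ± 0.36 and Cd4 at -0.19 ± 0.16. Nor was the interferon list (median 0.11 over 16 members, adjusted p = 0.975), where camera and fry differed in sign and Gbp3 had -0.77 ± 0.22, Gbp2 -0.60 ± 0.20 and Oas1a 0.82 ± 0.38. Ifi44 was at least 2.34-fold higher, being not well above background on any young array.

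Nerve, tendon and blood markers were lower in old muscle. The Schwann cell and nerve list fell (median -0.74 over 11 members, camera adjusted p = 0.00260, adjusted p = 0.187 with an estimated correlation, fry adjusted p = 0.0111). Prx fell over all genes and 7 members fell when adjusted over the list alone, among them Mag (-0.94 ± 0.15) and the Schwann cell regulator Sox10 (-0.92 ± 0.17). The myelin protein gene Mbp rose over the list alone (1.33 ± 0.18), although its 3 probes ran from -0.03 to 1.33. With normexp the medians of the Schwann cell and tendon lists were -0.44 and -0.85. The tendon and cartilage list fell (median -1.36 over 10 members, camera adjusted p = 0.00327, adjusted p = 0.270 with an estimated correlation, fry adjusted p = 0.0362). Kera fell over all genes, and 7 members fell over the list alone, with Chad at -2.16 ± 0.39 and Fmod at -1.30 ± 0.32. The matrix protein Cilp (0.94 ± 0.18) and Scx, a transcription factor of tendon cells (1.35 ± 0.40), rose over the list alone. The erythrocyte list fell (median -1.08 over 5 members, camera adjusted p = 0.00366, adjusted p = 0.351 with an estimated correlation, fry adjusted p = 0.103), with Hba-a1 at -1.20 ± 0.32, Hbb-bt at -1.03 ± 0.34, Alas2 at -1.26 ± 0.42 and Hbb-b1 at -1.08 ± 0.42. When adjusted over the list alone 4 fell. The globin probes may share signal between copies.

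**Figure D3:**
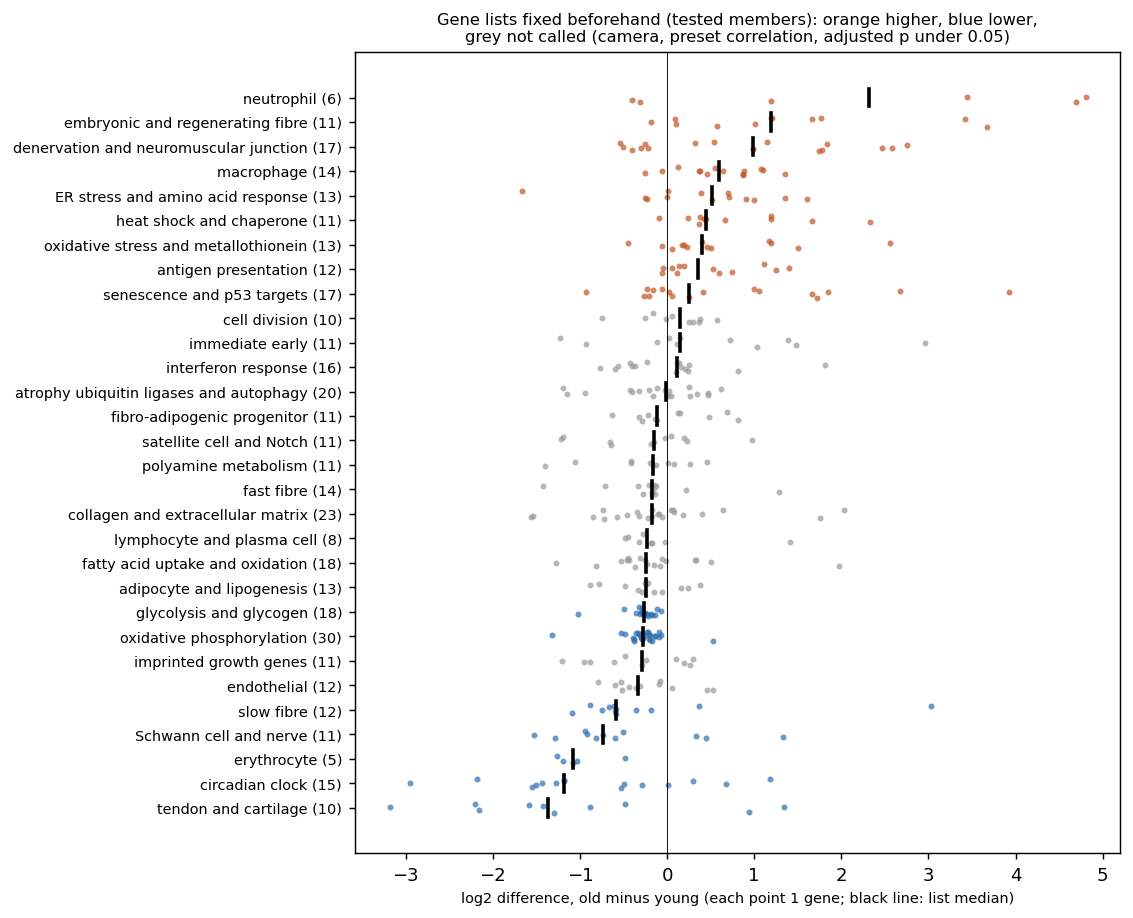
Log2 difference, old minus young (x axis), of each tested member of the 30 gene lists (y axis, tested members in brackets), with a black line at each list's median. Orange lists were called higher and blue lists lower by camera with a preset correlation, and grey lists were not called. The medians run from -1.36 in the tendon and cartilage list to 2.32 in the neutrophil list, whose points spread widely.

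Stress and clock genes also differed between the ages. In the senescence list (median 0.25, mean 0.75 over 17 members, camera adjusted p = 0.00327, adjusted p = 0.351 with an estimated correlation, fry adjusted p = 0.145) the cell-cycle inhibitor gene Cdkn2a was 6.38-fold higher (2.67 ± 0.25, limma adjusted p = 0.0214). Mmp3 (3.93 ± 0.89, well above background on 2 of 3 young arrays), Trp53 (1.05 ± 0.28) and Gdf15 (1.73 ± 0.48) rose when adjusted over the list alone. The median was 0.10 with median centring, 0.43 without young replicate 2, 0.38 without old replicate 1 and 0.51 without old replicate 2. Heat shock genes rose (median 0.45 over 11 members, camera adjusted p = 3.44e-04, adjusted p = 0.351 with an estimated correlation, fry adjusted p = 0.203), with Hspa1a at 2.33 ± 0.62, Hspb8 at 1.67 ± 0.51, Hspb7 at 1.20 ± 0.44 and Hspa1l at 0.66 ± 0.29, but 0 members passed singly even when adjusted over the list alone. The call was lost with the slide row as a block (median 0.08, adjusted p = 0.259), and without old replicate 3 the median was 0.24. Old replicate 3 had the highest median of the members, centred in the same way, in the heat shock (0.68), senescence (0.87) and ER stress (0.54) lists, against at most 0.13, 0.23 and 0.06 on the other old arrays. Without it these lists stayed called. The ER stress list rose (median 0.52 over 13 members, camera adjusted p = 0.00366, adjusted p = 0.351 with an estimated correlation, fry adjusted p = 0.0927). Sdf2l1 (1.60 ± 0.22) and Xbp1 (adjusted p = 0.142 over all genes and 0.0145 over the list) rose over the list alone, beside Pdia4 (1.36 ± 0.42) and Hspa5 (0.72 ± 0.25), and the median was 0.19 with the slide row as a block. The oxidative stress list rose (median 0.40 over 13 members, camera adjusted p = 0.00740, adjusted p = 0.351 with an estimated correlation, fry adjusted p = 0.210) but not without young replicate 3 (0.0852), and its median was 0.25 with median centring and without old replicate 3. Of its members 0 passed singly, also when adjusted over the list alone. The metallothionein gene Mt2 had 2.56 ± 0.73, Nqo1 0.50 ± 0.20 and Sod2 -0.44 ± 0.15, and Srxn1, with a fold of 2.83 (adjusted p = 0.381), was highest on old replicate 3. The circadian clock list fell (median -1.18 over 15 members, camera adjusted p = 0.00451, adjusted p = 0.351 with an estimated correlation, fry adjusted p = 0.0927). Adjusted over the list alone, 8 members fell, among them Bhlhe41, Hlf (-1.55 ± 0.32) and Dbp (-2.18 ± 0.52), and 2 rose, among them Arntl (1.18 ± 0.21), which encodes the clock activator BMAL1. With the slide row as a block the clock list was not called (median -0.51, adjusted p = 0.356). Its median was -0.54 with normexp, -0.52 with either other filter and -0.76 without young replicate 1.

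The remaining lists were not called. For collagen and matrix genes the median was -0.18 over 23 members (adjusted p = 0.309), with Col1a2 at -1.54 ± 0.36, Col1a1 at -1.56 ± 0.56, Postn at -0.57 ± 0.21 and Timp1 at 2.03 ± 0.68. With the slide row as a block (0.00846) and without old replicate 3 (0.0260) that list was called lower. The satellite cell and Notch list (median -0.15 over 11 members, adjusted p = 0.309) held Hey1 at -1.22 ± 0.29, Calcr, well above background on 1 of 3 old arrays, at -1.19 ± 0.45, Heyl at -0.66 ± 0.25 and Notch3 at -0.64 ± 0.25. Endothelial genes had a median of -0.34 over 12 members (adjusted p = 0.0682), with Cdh5 at -0.79 ± 0.22, Esam at -0.52 ± 0.17, Flt1 at -0.60 ± 0.24 and Kdr at -0.36 ± 0.18. They were called lower with normexp (0.0420), no filter (0.0108), every probe (0.0383) and array weights (0.0158), without young replicate 3 (0.0197) and without old replicate 1 (0.0207). Adipocyte genes had a median of -0.24 over 13 members (adjusted p = 0.309), with Fasn at -0.78 ± 0.27, Cfd at -0.34 ± 0.21, Plin1 at -0.48 ± 0.32 and Lipe at 0.38 ± 0.26, and were called lower with array weights (0.0329) and without old replicate 1 (0.0139). The fibro-adipogenic progenitor list (adjusted p = 0.975) had a median of -0.12 but a mean of 0.05. Over the alternatives, none of which called this list, the median ran from -0.34 to 0.31. Its member Gsn had -0.63 ± 0.23, with 2 probes at -5.29 and -0.63, beside Ly6a (0.48 ± 0.24), Dpt (0.81 ± 0.52) and Mfap5 (-0.33 ± 0.22).

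Immediate early genes had a median of 0.15 over 11 members (adjusted p = 0.159). Atf3 (2.96 ± 0.79) and Junb (1.48 ± 0.44) rose and Nr4a1 (-1.23 ± 0.35) fell when adjusted over the list alone, beside Fos at 1.03 ± 0.39. The list was called higher without old replicate 2 (0.0235). Imprinted growth genes had a median of -0.28 over 11 members (adjusted p = 0.164), with Plagl1 at -1.20 ± 0.31 (4 probes, from -1.26 to -0.25), Peg3 at -0.96 ± 0.32, Meg3 at -0.89 ± 0.33 and Cdkn1c at -0.61 ± 0.28, and were called lower with no filter (0.0351). Cell division genes had a median of 0.15 over 10 members (adjusted p = 0.373), with Mcm6 at 0.57 ± 0.16, Ccnb2 at -0.74 ± 0.33, Cdc20 at 0.36 ± 0.21 and Mcm3 at -0.25 ± 0.16. Polyamine genes had a median of -0.16 over 11 members (adjusted p = 0.334), with Amd2 at -1.06 ± 0.33 (3 probes, from -2.29 to -1.06), Smox at -1.40 ± 0.61, Azin2 at -0.42 ± 0.27 and Odc1 at -0.42 ± 0.32, and were called lower with the slide row as a block (0.0313).

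A further count took genes whose probes were not well above background on any array of an age while a probe was well above background on all 3 arrays of the other. There were 152, of which 86 were measured in old muscle and 66 in young muscle. Leaving out an array loosens this rule, so the count could only stay or rise, and its rise is no result. It ran from 249 without young replicate 3 (126 old, 123 young) to 399 without old replicate 1. The balance turned without young replicate 2 (111 old, 150 young) and without old replicate 1 (181 old, 218 young). The larger number in old muscle thus did not hold in all of these looser counts. It was 162 to 94 without young replicate 1, 206 to 99 without old replicate 2 and 145 to 115 without old replicate 3.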

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

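The negative control spots, which enter no comparison, had a mean signal of 61.3 on old replicate 1 against 51.9 to 55.1 on the young arrays, and this rule was devised after the values were seen. Old replicates 2 and 3 lay within the young range.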

How the results depend on the processing

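The called genes that the naming rule selects kept their sign in all alternatives that tested them. Gdf5 and Cd101 also kept an adjusted p under 0.05 in all of theirs (18 and 14, with highest values of 0.0326 and 0.0476). Over all genes that the naming rule selects, its list members included, 2251 results stayed on their side of the threshold, 151 lost it, 28 gained it and 0 reversed. The 2251 include genes called in neither fit, so they do not measure how firm the calls were. By definition the 151 losses can fall only on genes called in the main fit. Of 18 alternatives, Krt18 passed in 12, and Bhlhe41, Col22a1 and Prx in 9 each. For the lists 541 results stayed, 36 lost, 21 gained and 2 reversed, with the estimated correlation and fry included. The 541 include lists called in neither fit. The count of 53 genes, all of at least 2-fold, was 8 with no filter on dim probes, where more genes were tested (36717), and 35 with probes well above background on all arrays. Array weights gave 194 genes, 189 of them at 2-fold. Leaving out an array gave 1 to 186 genes, and the same range at 2-fold. Quantile normalization, median centring, normexp, the authors' values, mean probes, every probe and trend with robust gave 42, 42, 61, 51, 53, 75 and 62. With the replicate number as a block 5 genes passed, also at 2-fold, and 16 lists. The deviations of young and old arrays with the same number correlated at -0.06, -0.27 and 0.03, and none of the 3 young arrays correlated best with its own number. This shows no pairing, but 3 arrays per age are too few to exclude it, and the labels do not say whether the numbers pair the samples. The number of called lists was 13 to 20 under the other settings, 7 by fry and 0 with an estimated correlation. With the slide row as a block the atrophy list reversed to a median of 0.48 (adjusted p = 8.69e-04) and the slow fibre list, at a median of -0.23, had the opposite test direction (adjusted p = 0.926). That block leaves 1 old array against the young ones. Genes measured in 1 age only were 152, and 211 with the weaker detection flag (106 old, 105 young). They were 249 to 399 without an array, which loosens the rule and can only raise the count. Where a setting changed a count, the cause was not tested beyond the numbers of genes and arrays given.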

Other observations

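The tests on the neutrophil, tendon and clock patterns were chosen after their results were seen, and the genes and regions named in the next paragraphs were chosen after their values were seen.

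Other genes past limma's adjusted p of 0.05 in old muscle fall outside the lists and the naming rule. Gdf7, which like Gdf5 belongs to the bone morphogenetic protein family, had a log2 difference of 2.12 ± 0.18 and was well above background on 2 of 3 young arrays. The decoy receptor genes Tnfrsf22 and Tnfrsf23 had 1.66 ± 0.17 and 1.65 ± 0.19. The myeloid receptor genes Clec4d and Pirb had 2.60 ± 0.26 and 1.43 ± 0.18, and the salt-inducible kinase gene Sik1 1.60 ± 0.15. Among genes measured in old muscle only, Krt8, the keratin that pairs with Krt18, was at least 5.36-fold higher, and the chemokine Ccl12 at least 4.77-fold. Padi4, a citrullinating enzyme of neutrophils, was at least 2.12-fold higher by the probe tested (log2 difference 1.93), being not well above background on any young array. Its other kept probe gave 0.62. Limma's adjusted p was 0.0561 for Krt8, 0.142 for Ccl12 and 0.0263 for Padi4. Among genes measured in young muscle only, the peptide gene Grp was at least 5.03-fold and Cilp2 at least 5.01-fold higher in young muscle, with adjusted p of 0.0972 and 0.138.

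The called features include 3 probes for non-coding regions, whose coordinates are those of the probe names on mm9. The region on chromosome 18, 3003075 to 3016150, reverse strand, had a log2 difference of 1.85 ± 0.22 (limma adjusted p = 0.0385). Those on chromosome 9, 68349343 to 68411643, reverse strand, and chromosome 16, 9158862 to 9162427, forward strand, were at least 1.64-fold and at least 1.47-fold higher in old muscle (adjusted p = 0.0349 and 0.0409).

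Of 6 neutrophil transcripts 3 rose in old muscle and 1, Camp, fell when adjusted over the list alone, and the list's call was lost with an estimated correlation (adjusted p = 0.351). More blood in the old samples would raise erythrocyte transcripts as well, but their list had a median of -1.08 and was called lower. This argues against more blood as the whole cause, but does not address how many neutrophils that blood held. The median of the erythrocyte members, each centred on its mean over the 6 arrays, was -0.12 on young replicate 3. It was -0.17 and -0.28 on old replicates 1 and 2. The erythrocyte call was lost with an estimated correlation (adjusted p = 0.351) and by fry (0.103), although all 5 members had negative values. For S100a8 and S100a9 alone, the higher low-end signal on old replicate 1 is argued against too, since both passed without that array (limma adjusted p up to 0.00929). Retnlg, not well above background on any young array, was not tested without it. A change with age in the neutrophils held in the tissue, or in the cells that make these transcripts, may be involved and was not tested.

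Tendon transcripts were lower in old muscle. Less tendon in the old samples and a change with age in tendon cells cannot be told apart. Over the list alone 2 members, Cilp and Scx, rose, but both could have other cellular sources, so this decides nothing about the share of tendon. A heterogeneity test, run without Cilp (Cochran Q 91.7), on all members (Q 199) and on the 8 lower ones (Q 43.6), has no exact p with 3 arrays per age. The list's call was lost with an estimated correlation (adjusted p = 0.270).

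Clock transcripts were shifted in old muscle, with Arntl higher and Dbp lower, 3.36 apart on the log2 scale. These genes peak at opposite hours, so a different hour of collection could give this, as could age, and the labels used here give no hour. The 2 explanations cannot be told apart. The list's call was lost with an estimated correlation (adjusted p = 0.351), by fry (0.0927) and with the slide row as a block (0.356).

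Splitting the 6 arrays into 3 and 3 can be done in 10 ways, too few for a share under 0.05. The real split gave 53 genes, also at 2-fold, against 1 at most in the others, and 16 lists against 8 at most, so 1 of the 10 splits gave as many in each case. At an unadjusted p under 0.05 the real split gave 3021 genes, and grouping young replicates 1 and 2 with old replicate 1 gave 2439.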
